A study of Homo sapiens with 18 samples.

How the data were processed

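Expression was measured in 18 cultures of one cell line, 6 in each of 3 groups, on arrays with 54613 probe sets in the deposited table. Groups and replicate numbers came from the sample titles. Titles and series text name the beta receptor, the growth protocol the alpha receptor, and the titles were followed. Per the labels' protocols, total RNA was extracted with a column kit, 20 ng of it was amplified into biotin-labelled cDNA, and the medium held 10% CD-FBS and no phenol red. The deposited values are intensity on a linear scale, already normalized by the authors; GCRMA, a background correction and quantile normalization that uses probe sequence, is named per the submitters' processing notes, and its version is not given in the sources used here. The lowest intensity on each array was near 4.87 and the median near 5.03, so that most probe sets sat close to the lowest level of the table, where differences are compressed. Control probes of the array were not analysed here, so no measure of RNA quality came from them.

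Values were taken as log2 intensity after a floor of 1, with no further normalization. Probe sets were kept where log2 intensity was at least 5 on at least 6 of the 18 arrays, which left 12579 (23.0%). Gene symbols came from the platform annotation that was supplied, updated through gene numbers to the symbols of a current RefSeq table (GRCh38, used for names only): 41091 probe sets had 1 symbol, 1801 had several and 11721 had none here, and 41037 of the first matched by number. No genomic positions are given because the array table names no genome build. Of the kept probe sets 11038 had 1 symbol, 571 several and 970 none; the last 2 kinds were left out of the gene tests. Each gene was represented by its kept probe set with the highest mean over all arrays, giving 7114 genes, of which 2569 had several kept probe sets. No 2 arrays held the same values; the highest share of identical values between any pair was 2.12%.

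One model without covariates was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), and 3 comparisons were tested in it, two-sided: ERb against CMV, ERbDBD against CMV, and ERb against ERbDBD. A gene was called, and is said to have risen, fallen or changed, at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Adjusted p-values for genes are limma's throughout, errors of log2 changes are the model's standard errors, and intervals are 95%. Numbers paired the ERb arrays with the ERbDBD arrays, since after group means were removed all 6 pairs of equal number correlated above 0.1 (0.12 to 0.43, 3 best with their own number); neither group was paired with CMV by that measure (-0.29 to 0.20 for ERb, -0.09 to 0.37 for ERbDBD). The series text describes the repeats as independent and made on 6 different days, without saying that a replicate number is a day. The genes called in both comparisons against CMV were set against independent lists, against simulated unchanged groups sharing the CMV arrays, and against CMV arrays split 3 and 3.

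The genes named in the text followed a rule set before the data were examined: ESR2, then in each comparison the 8 called genes with the largest increase and the 8 with the largest decrease, the called members of a described list with the smallest p, up to 4 per direction, and the 5 genes with the largest mean change in each class of the receptor comparison. The rule was applied again with the doubted arrays left out; metallothioneins, the arrays' values of single genes, uncalled list members and the markers of the line are named outside it, after their values were seen. The 21 lists of pathways and complexes and 6 lists of cell markers were also written before the data were examined. Pathway lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 21 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. A list of genes induced by glucocorticoids and one of zinc-responsive genes were written after the largest changes had been seen and before either was tested.

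The procedure was tested on simulated data with 200 of 7114 genes changed, in 20 simulations. The spread of each gene came from the real arrays without ERb replicate 6 and ERbDBD replicate 6, and genes were drawn independently. The recovery therefore does not describe a fit that holds those 2 arrays. For ERb against CMV it recovered 82.5% of genes changed by log2 0.5, 98.4% at 1 and 99.9% at 2, with 4.98% of its calls false; for ERb against ERbDBD it recovered 80.9%, 98.2% and 99.8%, with 5.39% false. When 1 array of each group was exchanged in the simulation of ERb against ERbDBD, 0.0746%, 0% and 0.0758% were recovered, and the median fitted changes were 0.34, 0.67 and 1.33. In the test of lists, camera gave a shifted list a p of 3.88e-48, and 2% of 200 unchanged lists passed 0.05. The simulated genes were not correlated, so this test does not cover lists whose genes move together. For the classical estrogen receptor targets the estimated correlation was 0.12.

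Alternatives fixed before the data were examined were the replicate number as a block or as a random effect (limma with statmod 1.5.0), a fit of the 2 groups compared only, no filter and a stricter filter (log2 intensity of 7), the mean of a gene's probe sets, every probe set tested, median centring, quantile normalization, array weights, no variance trend, a 2-fold minimum, an adjusted p of 0.01, and leaving out each array and each replicate number. Leaving out ERb replicate 6 and ERbDBD replicate 6 together was added after seeing the data, as was the replicate block in that setting. Figures were drawn with matplotlib 3.10.9.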

Results

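MDA-MB-231 is a human breast cancer cell line of basal, mesenchymal character that lacks estrogen receptor alpha. Cells were given an adenoviral vector for 48 h, and the vector differed between 3 groups. In group CMV, named after the labels, it carried no insert. In group ERb it carried estrogen receptor beta per the titles, and in group ERbDBD a form of that receptor defective in ERE binding through a mutation the labels do not give, where an ERE is the DNA motif through which estrogen receptors contact many target genes. All groups then received 1 nM 17beta-estradiol, the natural ligand, for 6 h. By design the comparisons with CMV therefore concerned the presence of a receptor in ligand-treated cells, that of ERb with ERbDBD its form, and none the effect of estradiol. Replicate numbers paired ERb with ERbDBD and neither with CMV. Any handling that differed between CMV and receptor arrays would be counted with the receptor. Each group held 6 replicates, 18 arrays in all, and the series text places the repeats on 6 days. Total RNA was measured on 1-colour oligonucleotide arrays, and 7114 genes passed the intensity filter. Between 22.6% and 23.1% of probe sets reached the filter level on each array, and the number of arrays limits the precision.

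ESR2, the gene of estrogen receptor beta, had the largest change in both receptor groups. Its log2 intensity was 2.85 ± 0.16 (SD, n = 6) in CMV, 8.30 ± 0.51 (n = 6) in ERb and 8.21 ± 0.39 (n = 6) in ERbDBD. The rise over CMV was 43.8-fold in ERb (log2 5.45, SE 0.21, limma adjusted p = 7.21e-12) and 41.2-fold in ERbDBD (log2 5.36, SE 0.21, limma adjusted p = 9.57e-12). Single arrays ran from 2.74 to 3.07 in CMV, from 7.82 to 9.22 in ERb and from 7.59 to 8.62 in ERbDBD, so every receptor array lay above every CMV array. ERb and ERbDBD differed in ESR2 by 0.09 on the log2 scale (95% interval -0.35 to 0.52, adjusted p = 1). ESR2 shows that a receptor was present and not which of the 2 forms it was. Of the 6 probe sets of ESR2, 3 carried this signal and 3 stayed near the lowest level of the table in all groups. The labels' growth protocol names the alpha receptor instead. None of the 9 probe sets of ESR1, the alpha gene, passed the intensity filter, the highest value on any array was 3.01, and the largest difference of a receptor group from CMV was 0.05 (looked at after the data were seen). Within CMV, 4 of the 6 arrays lay within 0.01 log2 units of the group median for ESR2, PTPRE and MANEAL. For ESR2 no CMV array read more than 0.01 below that level, so smaller amounts may not be resolved and its folds over CMV are lower bounds. For PTPRE the lowest CMV array read 4.55 against a repeated 4.64, and for MANEAL 5.38 against 5.50. The repeated level was thus no floor for either gene, and the sizes of their folds are given as fitted and are uncertain. LOXL4 and RHOU were below the intensity filter level on all 6 CMV arrays and YPEL2 on 5, without a repeated level, and there differences are compressed, so the sizes of their folds over CMV are uncertain.

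The arrays labelled ERb replicate 6 and ERbDBD replicate 6 stood apart from the other arrays of their groups. LOXL4, a lysyl oxidase-like enzyme that cross-links collagen, read 8.85 to 9.30 on the other 5 ERb arrays and 5.01 on ERb replicate 6. On the ERbDBD arrays LOXL4 read 4.48 to 5.93 in the other 5 and 8.79 in replicate 6. YPEL2, a yippee-like family gene, read 7.27 to 8.08 on the other 5 ERb arrays and 5.99 on ERb replicate 6, against 5.05 to 5.25 and 8.25 for ERbDBD in the same order. RHOB read 8.91 to 9.06 on the other 5 ERb arrays and 11.32 on ERb replicate 6, against 10.82 to 11.26 and 9.31 for ERbDBD. RHOU read 3.34 to 4.09 and 5.47 for ERb, against 5.66 to 6.17 and 3.49 for ERbDBD. Results are given with all 18 arrays as labelled. Counts are repeated with both of these arrays left out, a setting chosen after seeing the data.

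**Figure D1:**
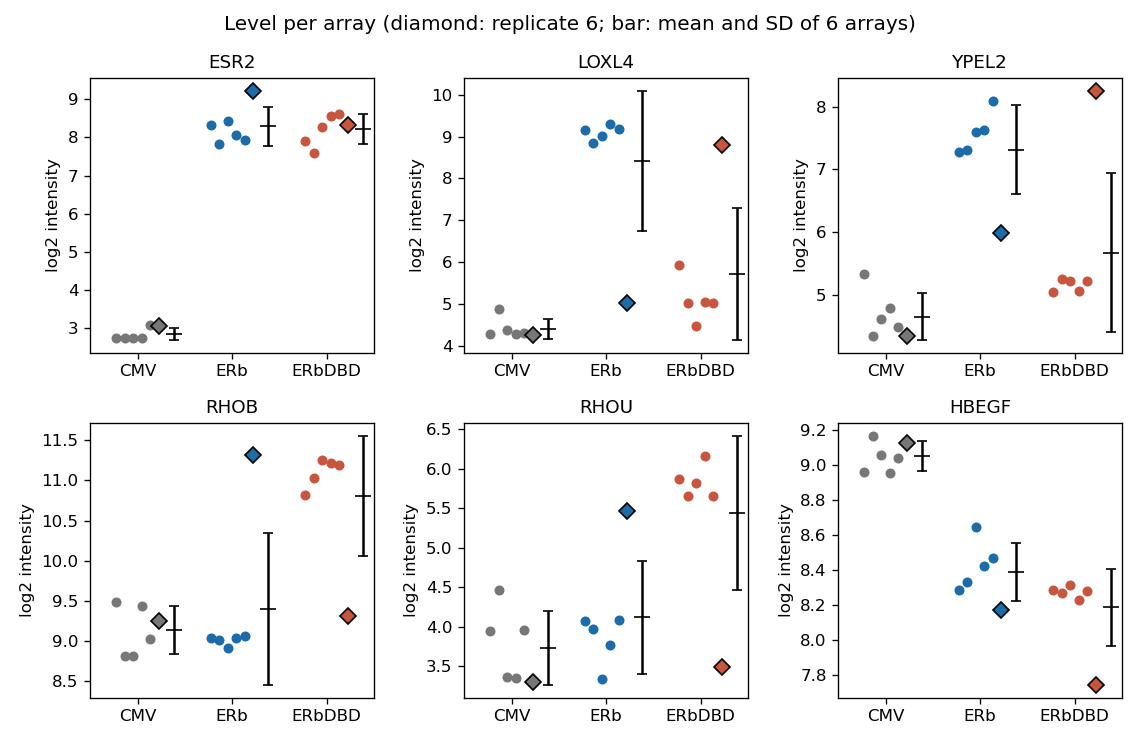
Log2 intensity of ESR2, LOXL4, YPEL2, RHOB, RHOU and HBEGF on each of the 18 arrays by group, with diamonds for replicate 6 and bars for the mean and SD of 6 arrays. The diamond of ERb lies at 5.01 for LOXL4 and 11.32 for RHOB and that of ERbDBD at 8.79 and 9.31, away from the other 5 arrays of its group, while HBEGF on all receptor arrays (7.74 to 8.65) lies below CMV (8.95 to 9.17).

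The comparison of ERb with CMV asks what the wild type receptor with its ligand changed in cells that lack it. LOXL4 rose 16.2-fold (log2 4.02, SE 0.71, adjusted p = 0.0050), or 26.0-fold with both arrays of number 6 left out (log2 4.70, SE 0.19, adjusted p = 1.78e-10), and YPEL2 rose 6.29-fold (log2 2.65, SE 0.46, adjusted p = 0.00422). PTPRE, a receptor-type tyrosine phosphatase, and MANEAL, an endomannosidase-like gene, rose 3.25-fold each (log2 1.70, SE 0.31 and 0.36). CRISPLD2, a secreted cysteine-rich protein, rose 3.09-fold, the Wnt ligand WNT9A 2.49-fold, and GREB1L, a relative of the estrogen-induced gene GREB1, 2.26-fold. The largest decreases among genes with 1 symbol were smaller. ADAMTS6, a secreted metalloproteinase, was 1.79-fold lower (log2 -0.84, SE 0.11, adjusted p = 0.000791), the noncoding RNA MIR100HG 1.76-fold and PLAUR, the urokinase receptor, 1.75-fold. The repressor KLF12 was 1.67-fold lower, CD274, the immune checkpoint ligand PD-L1, 1.63-fold, and HBEGF, a ligand of the epidermal growth factor receptor, 1.58-fold. DKK1, a secreted Wnt antagonist, was 1.56-fold lower and the adenosine receptor ADORA2B 1.54-fold lower.

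In total 108 genes changed between ERb and CMV, 56 higher and 52 lower, of which 14 rose and 0 fell at least 2-fold. An unadjusted p below 0.05 was found for 845 genes, where chance gives 355.7. The split became 89 higher and 32 lower with arrays centred on their medians, and 100 and 53 after quantile normalization. With both arrays of number 6 left out 280 genes changed, 151 higher and 129 lower, and 107 of the 108 were among them. The count was 196 without ERb replicate 6, 187 without ERbDBD replicate 6 and 71 without ERb replicate 3. The call of MANEAL was lost without ERb replicate 3 (adjusted p = 0.0537), and that of GREB1L without ERb replicate 1, 3 or 4 (highest adjusted p = 0.0537). MIR100HG was lost without CMV replicate 4, 5 or 6 or ERb replicate 5 (highest adjusted p = 0.0614). ADORA2B was lost without CMV replicate 1, 4, 5 or 6 or any of ERb replicates 1 to 5 (highest adjusted p = 0.0831). With every probe set kept regardless of intensity, MANEAL, GREB1L, MIR100HG, ADORA2B, WNT9A and CDKN1A did not pass, at adjusted p from 0.0566 for WNT9A to 0.122 for ADORA2B. With only these 2 groups fitted GREB1L and ADORA2B did not pass (adjusted p = 0.0564 each).

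Classical estrogen receptor targets, a list written before the data were examined, stood higher in ERb than in CMV as a set. Of 38 genes 14 were measured, 11 of the 14 had positive values, and the median log2 difference was 0.19. Camera gave an adjusted p of 0.000518 over 21 lists, with adjusted p = 0.265 with an estimated correlation, and fry gave 0.0668. None of the 14 passed the limma test over all genes. Adjusted over the list alone 1 did, C3, the central complement component, at log2 0.91 (SE 0.24). The luminal keratin KRT19 differed by 0.46, IGFBP4, a binding protein of insulin-like growth factors, by 0.33 and the protease gene CTSD by 0.29, none past the test. Leaving out both arrays of number 6, the camera adjusted p was 0.00326, or adjusted p = 0.170 with an estimated correlation, and fry gave 0.0125. In that setting C3 (log2 0.96, SE 0.25, adjusted p = 0.0350) and the growth factor gene TGFA (log2 0.34, SE 0.09, adjusted p = 0.0386) rose, 2 over all genes and 6 adjusted over the list alone. As labelled, in ERbDBD against CMV the list had a median of 0.10, 9 of 14 positive values, no member called over all genes or adjusted over the list alone, and a camera adjusted p of 0.0517. The direct comparison of ERb with ERbDBD gave a median of 0.11 and an adjusted p of 0.294. Leaving out both arrays, PTGES (log2 0.82, SE 0.14, adjusted p = 0.00310) and FKBP5 (log2 0.21, SE 0.04, adjusted p = 0.0138) rose in ERbDBD against CMV, with 3 higher and 1 lower adjusted over the list alone, a median of 0.04 and a camera adjusted p of 0.345. In that setting 1 was higher and 2 were lower in ERb than in ERbDBD (5 and 2 adjusted over the list alone), with a median of 0.26 and a camera adjusted p of 0.160.

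**Figure D2:**
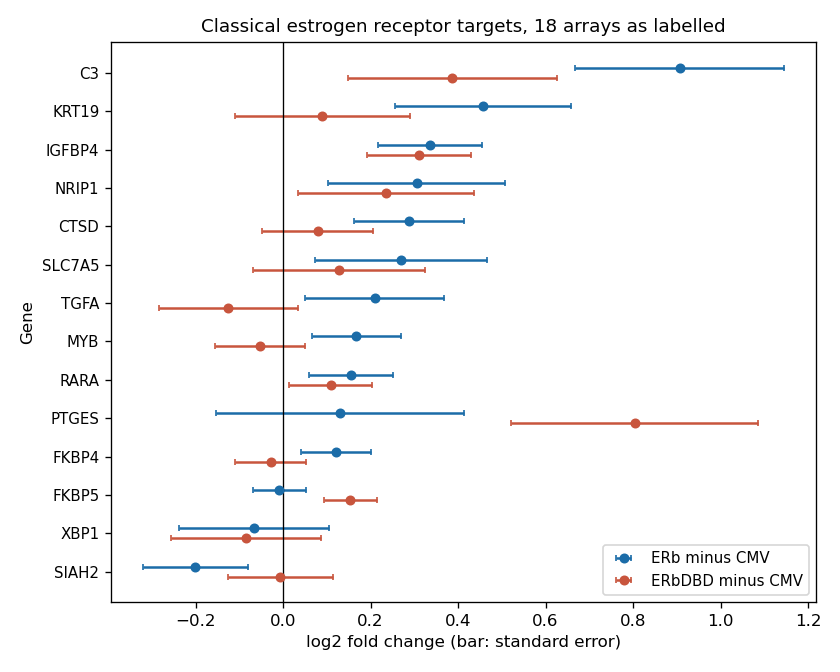
Log2 fold change over CMV of the 14 measured classical estrogen receptor targets in ERb and ERbDBD, all 18 arrays as labelled, with bars for the standard error. C3 has the largest value in ERb at 0.91 and PTGES the largest in ERbDBD at 0.80, neither past the test over all genes.

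Single members of other lists changed in ERb. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose (log2 0.90, SE 0.19, adjusted p = 0.0179), the 1 called of 13 CDK inhibitors and p53 pathway genes. Adjusted over the list alone 1 was higher and 2 were lower, BTG1 at -0.38 and GADD45A at -0.46. Among 20 immediate-early genes the AP-1 member FOSL2 (log2 0.43, SE 0.06) and the zinc finger factor KLF10 (log2 0.65, SE 0.11) rose, and adjusted over the list alone 3 were higher and 4 lower. Of 24 adhesion and matrix genes the matricellular protein gene CCN2 fell by 0.49 (SE 0.10) and the Notch ligand gene JAG1 fell by 0.20 (SE 0.04), with 3 lower adjusted over the list alone. The hexokinase gene HK1 rose (log2 0.66, SE 0.13, adjusted p = 0.0101), the 1 called of 23 hypoxia and glycolysis genes and 1 adjusted over the list alone. BIRC2, an inhibitor of apoptosis, fell by 0.30 (SE 0.06), 1 of 17 apoptosis regulators and 1 adjusted over the list alone. JAG1 and BIRC2 did not pass with arrays centred on their medians (adjusted p = 0.255 and 0.142). TNFAIP2, a gene induced by tumor necrosis factor, rose (log2 0.78, SE 0.09), 1 of 10 NF-kB and cytokine genes and 1 adjusted over the list alone. PLAUR was the 1 called of 17 mesenchymal and invasion genes, where 1 was higher and 5 lower adjusted over the list alone.

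Camera called none of these 7 lists in ERb against CMV, and fry gave apoptosis regulators an adjusted p of 0.0189. With both arrays of number 6 left out camera placed apoptosis regulators (adjusted p = 0.0309, median -0.07) and hypoxia and glycolysis (adjusted p = 0.0266, median -0.14) lower. With an estimated correlation neither was called, at adjusted p = 0.170 and adjusted p = 0.859. Of the 2 lists, fry called only apoptosis regulators there (adjusted p = 0.0102). In that setting the glucose transporter gene SLC2A1 fell by 0.43 (SE 0.07) and ADM, adrenomedullin, fell by 0.22 (SE 0.06), while HK1 rose (log2 0.74, SE 0.09).

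The 13 lists without a called member in ERb against CMV, besides the classical targets, had medians from -0.08 for adenovirus entry receptors and antiviral sensors to 0.06 for cholesterol synthesis. They also held reported AP-1 or Sp1 targets, nuclear receptors and coregulators, G1/S, G2/M, interferon response, epithelial genes, TGF-beta response, unfolded protein response, heat shock, ribosomal proteins and oxidative phosphorylation. Adjusted over the list alone, 1 epithelial gene was higher (MUC1, 0.45) and 1 lower (OCLN, -0.46), and 2 TGF-beta genes were lower (TGFB2, -0.34, and TGFBR2, -0.37). Of the markers of the line itself 8 of 10 were measured, among them VIM, CD44, AXL, CAV1 and PLAU, and none was called. Their median was -0.13 in ERb against CMV (camera p = 0.000195, p = 0.00155 with an estimated correlation). In ERbDBD against CMV it was -0.09 (camera p = 0.0122, p = 0.0203 with an estimated correlation). PLAU, the urokinase gene, differed by -0.64 in ERb without passing. Markers of other cells were mostly below the filter, with 3 kept for luminal breast lines (EPCAM, KRT19 and XBP1), 1 for HEK293 (ZIC2), 1 for fibroblasts (COL1A1), 2 for leukocytes (CD74 and LAPTM5) and 0 for endothelium. None of these was called.

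The comparison of ERbDBD with CMV asks what the receptor changed without binding to EREs. CRISPLD2 rose 3.95-fold (log2 1.98, SE 0.21, adjusted p = 6.99e-05), RHOU 3.28-fold (log2 1.71, SE 0.40, adjusted p = 0.0488) and RHOB 3.18-fold (log2 1.67, SE 0.38, adjusted p = 0.0431). MT1X, a metallothionein, rose 1.89-fold (adjusted p = 0.0499), the thromboxane receptor gene TBXA2R 1.83-fold, TNFAIP2 1.80-fold and the histone demethylase gene KDM4B 1.75-fold. The 3 kept probe sets of TBXA2R differed in sign. HBEGF was 1.82-fold lower (log2 -0.86, SE 0.10, adjusted p = 7.89e-05), ADAMTS6 1.75-fold (log2 -0.81, SE 0.11) and MIR100HG 1.75-fold. KLF12 was 1.57-fold lower, CD274 1.55-fold, the cytokine gene IL18 1.55-fold, PLAUR 1.51-fold and DKK1 1.49-fold.

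In total 65 genes changed between ERbDBD and CMV, 32 higher and 33 lower, of which 4 rose and 0 fell at least 2-fold, and 701 had an unadjusted p below 0.05. The split became 54 higher and 22 lower with arrays centred on their medians, and 58 and 34 after quantile normalization. With both arrays of number 6 left out 204 genes changed, 102 in each direction, and 64 of the 65 were among them; PLAUR was the exception (adjusted p = 0.0617). The count was 135 without ERbDBD replicate 6 and 41 without ERbDBD replicate 3. For several genes the adjusted p crossed the threshold when 1 array was left out, while the log2 change kept its direction. Over 18 such fits it ran from 1.58 to 1.97 for RHOB, 1.57 to 2.10 for RHOU, 0.82 to 1.14 for MT1X, 0.71 to 0.85 for KDM4B, -0.66 to -0.53 for PLAUR and -0.92 to -0.65 for MIR100HG. RHOB passed only without ERb replicate 6 or ERbDBD replicate 6 among these fits (highest adjusted p = 0.113). RHOU and MT1X passed only without those or CMV replicate 2 (highest adjusted p = 0.123 and 0.128). PLAUR passed only without CMV replicate 2 or 3, ERb replicate 1 or 6, or ERbDBD replicate 5 (highest adjusted p = 0.125). KDM4B passed only without CMV replicate 5, ERb replicate 1, 2, 4, 5 or 6, or ERbDBD replicate 6 (highest adjusted p = 0.102). MIR100HG was lost without CMV replicate 1, 2, 4, 5 or 6 or ERbDBD replicate 1, 3 or 5 (highest adjusted p = 0.0971). With every probe set kept regardless of intensity these 6, PHLDA1, IL18 and FOSL2 did not pass, at adjusted p from 0.0567 for IL18 to 0.187 for RHOU. With only these 2 groups fitted RXRA, MIR100HG, PLAUR, RHOU and MT1X did not pass, at adjusted p from 0.0562 for RXRA to 0.139 for MT1X. FOSL2 did not pass with the mean of its probe sets (adjusted p = 0.277). Over every probe set MT1X, RHOU and PLAUR did not pass (adjusted p from 0.0501 to 0.0508), without a variance trend RHOU (adjusted p = 0.0555) and MT1X (adjusted p = 0.0569), and with array weights PLAUR (adjusted p = 0.0728).

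Metallothioneins, small metal-binding proteins encoded by near-identical genes, had positive values against CMV in all 7 measured members on the ERbDBD arrays. The median was 0.78 (0.68 to 0.96), and 1 of the 7, MT1X, passed the test. In ERb against CMV all 7 were positive as well (median 0.44, 0.33 to 0.52) and 0 passed in limma. As labelled 0 of 7 passed in ERb against ERbDBD (median -0.40, smallest adjusted p = 0.866). With array weights 6 of the 7 were called lower in ERb than in ERbDBD (median -0.60), and all 7 once the 3 arrays of number 6 were left out. Without ERbDBD replicate 6 alone 1 was called, and without ERb replicate 6 alone 0 in limma (smallest adjusted p = 0.453). With arrays centred on their medians 7 passed in ERbDBD against CMV, and after quantile normalization 6. With both arrays of number 6 left out 7 of 7 rose against CMV (median 0.97, 0.85 to 1.19), none passed in ERb against CMV (median 0.35), and 7 of 7 were lower in ERb than in ERbDBD (median -0.68). MT1F rose 2.29-fold in that setting (log2 1.19, SE 0.15, adjusted p = 0.000263) and MT2A by log2 0.85 (SE 0.12). The family was singled out after its values were seen, and since its members can share probe targets the 7 are not separate measurements.

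As labelled, few members of the lists changed in ERbDBD. Among 20 immediate-early genes DUSP1, a phosphatase of stress-activated kinases, rose (log2 0.79, SE 0.13, adjusted p = 0.00477) with FOSL2 (log2 0.33, SE 0.06). PHLDA1 fell by 0.29 (SE 0.06, adjusted p = 0.0202), and was lost without CMV replicate 3 (adjusted p = 0.0525) or ERbDBD replicate 3 (adjusted p = 0.0634). Of this list 3 were higher and 4 lower adjusted over the list alone. RXRA, a heterodimer partner of many nuclear receptors, rose (log2 0.39, SE 0.07, adjusted p = 0.0109), the 1 called of 18 nuclear receptors and coregulators and 1 adjusted over the list alone. BIRC2 fell by 0.30 (SE 0.06), 1 of 17 apoptosis regulators, with 3 lower adjusted over the list alone. BIRC2 and PHLDA1 did not pass with arrays centred on their medians (adjusted p = 0.211 and 0.124). PLAUR was the 1 called of 17 mesenchymal and invasion genes (1 higher and 3 lower adjusted over the list alone), and TNFAIP2 the 1 called of 10 NF-kB and cytokine genes (1 higher and 2 lower adjusted over the list alone). None of 24 adhesion and matrix genes was called, and 4 were higher and 3 lower adjusted over the list alone. Camera called none of the 21 lists (smallest adjusted p = 0.0517). The 15 lists with no called member besides the classical targets had medians from -0.16 for interferon response to 0.02 for reported AP-1 or Sp1 targets. When both arrays of number 6 were left out more members were called. Of CDK inhibitors and p53 pathway genes 4 were lower, the same 4 adjusted over the list alone: BTG1 at -0.37, PLK2 at -0.34, CDKN1B at -0.22 and MDM2, whose 3 kept probe sets differed in sign, at -0.16. Of NF-kB and cytokine genes 1 was higher and 3 were lower (3 and 5 adjusted over the list alone), IL24 at -1.41, CXCL8 at -0.57 and CXCL3 at -0.50. Of immediate-early genes 3 were higher, KLF10 now among them at 0.31, and 3 were lower, DUSP4 at -0.41, PHLDA1 at -0.32 and IER3 at -0.28 (4 and 5 adjusted over the list alone). Camera called no list there either (smallest adjusted p = 0.345).

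Wild type and mutant receptor were compared directly, which tests whether a response differed with the ability to bind EREs. As labelled, 0 genes passed (limma, smallest adjusted p = 0.198), and 399 had an unadjusted p below 0.05 where chance gives 355.7. The largest differences had wide intervals. LOXL4 was higher in ERb by 2.70 (95% interval 1.21 to 4.19, adjusted p = 0.415), YPEL2 by 1.64 (0.67 to 2.60, adjusted p = 0.488) and PTPRE by 1.22 (0.57 to 1.88, adjusted p = 0.364). RHOB differed by -1.41 (-2.21 to -0.61, adjusted p = 0.488) and RHOU by -1.32 (-2.16 to -0.49, adjusted p = 0.488). Camera called none of the 21 lists (smallest adjusted p = 0.0817). None of 20 immediate-early genes was called, and 3 were higher and 5 lower adjusted over the list alone. The count of 0 became 82 without ERb replicate 6, 92 without ERbDBD replicate 6 and 225 without both, 139 higher and 86 lower in ERb. Leaving out any other single array gave 0.

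With both arrays left out, 5 ERb arrays and 5 ERbDBD arrays differed most in LOXL4, which was 16.0-fold higher in ERb (log2 4.00, SE 0.20, adjusted p = 4.95e-09). The deubiquitinase gene OTUB2 was 7.69-fold higher (SE 0.53 on the log2 scale), RGS4, a regulator of G protein signalling, 6.33-fold, and YPEL2 5.34-fold. PTPRE was 3.42-fold higher and MANEAL 3.41-fold. For each, 1 of the 5 ERbDBD arrays lay within 0.01 of the repeated CMV level, so these sizes are uncertain. The transglutaminase gene TGM2 was 3.42-fold higher and the endothelial lipase gene LIPG 3.20-fold. RHOB was 4.27-fold lower in ERb (log2 -2.09, SE 0.13, adjusted p = 4.89e-08), RHOU 3.96-fold and the lipid flippase gene ATP10D 2.23-fold. EPAS1, the hypoxia-inducible factor HIF-2 alpha, was 2.16-fold lower, the prostaglandin E synthase gene PTGES 2.04-fold, PDLIM1 and AKAP12 2.01-fold each and FOXQ1 at least 2.01-fold, since 4 of its 5 ERb arrays lay at a repeated low level. RGS4 and LIPG were below the intensity filter level on all 5 ERbDBD arrays, TGM2 on 4 of them and RHOU on all 5 ERb arrays, so the sizes of these folds are uncertain as well. Of the 225 genes, 115 were also called in ERb against CMV and differed from ERbDBD in that same direction (96 higher, 19 lower). In ERbDBD against CMV 70 were called and differed from ERb in that same direction (48 higher, 22 lower). LIPG, VPS26C, SDC2 and RBM24 were called in both against CMV in opposite directions, 4 genes where independent lists give 3.98 and split CMV arrays a median of 1.5. IL24, a cytokine gene, was 2.66-fold lower in ERbDBD than in CMV (log2 -1.41, SE 0.22) and differed by -0.26 in ERb. The chemokine gene CXCL8 fell by 0.57 in ERbDBD against CMV (SE 0.09). Because both arrays were left out on account of their values, these p-values overstate the evidence.

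**Figure D3:**
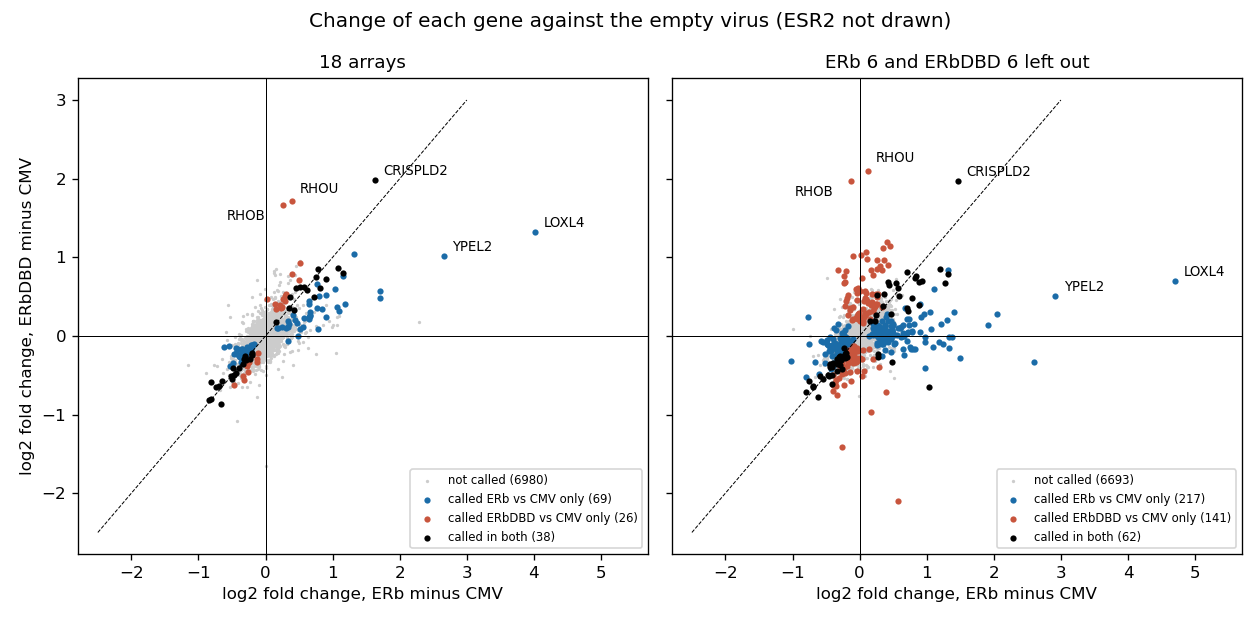
Log2 fold change over CMV of each gene in ERb (horizontal) and ERbDBD (vertical), with 18 arrays on the left and with ERb replicate 6 and ERbDBD replicate 6 left out on the right; colours mark the calls and the dashed line marks equal change. LOXL4 and YPEL2 lie below the line and RHOB and RHOU above it in both panels, and the vertical value of LOXL4 is 1.32 on the left and 0.70 on the right.

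Part of the response was called in both receptor groups. As labelled, 39 genes were called in both against CMV in the same direction (17 higher, 22 lower) and none in opposite directions. ESR2, CRISPLD2, KDM4B, TBXA2R and ADAMTS6 had the largest mean change among them. KDM4B rose 2.23-fold in ERb and 1.75-fold in ERbDBD, TNFAIP2 1.72-fold and 1.80-fold, and HBEGF was 1.58-fold and 1.82-fold lower. Both comparisons share the CMV arrays, and any difference in the handling of those arrays would appear in both. Without ESR2, 16 higher and 22 lower shared genes stood against 0.24 and 0.241 for independent lists and 0 in simulated unchanged groups. Groups without any change give few calls, so that simulated 0 cannot show how much overlap the shared arrays create. With the CMV arrays split 3 and 3 between the comparisons the medians were 6 and 5. Each comparison then had 3 controls and less power to call genes, so the drop cannot be credited to the shared arrays alone. Across genes, which are not independent replicates, the fold changes had a covariance of 0.0162 against 0.00844 simulated (highest simulated 0.0261), at r = 0.64 against 0.52. When both arrays of number 6 were left out 59 genes were called in both in the same direction, 26 higher and 33 lower. Without ESR2 these were 25 and 33, against 2.13 and 1.85 for independent lists and 13 and 14 with split CMV arrays.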

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

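The tests of exchanged labels, of infection and of mixed RNA in the arrays of number 6 were chosen only after the result was seen, as was leaving both arrays out; the tests of other splits of the samples and of the metallothioneins were written down before their outcomes.

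On 45 occasions 1 array lay far from the other 5 of its group for a named gene, among 138 group and gene combinations tested, where chance flags about 1 in 20 groups, or 6.9 here. Of these, 19 were in ERb replicate 6, 20 in ERbDBD replicate 6 and 6 in all other arrays, and many of the genes were picked because they differ between the receptors without those arrays. In ERb replicate 6 the log2 intensities high in their group were ADORA2B 10.40, AKAP12 11.09, CRISPLD2 9.64, FOXQ1 7.46, PTGES 11.001, RHOB 11.32, RHOU 5.47 and TNFAIP2 10.49. Those low in their group were FST 7.62, IL24 6.15, KITLG 7.44, LOXL4 5.01, MANEAL 5.48, OTUB2 6.92, PTPRE 5.27, RBM24 10.38, RGS4 3.71, SDC2 6.59 and VPS26C 8.08. In ERbDBD replicate 6 the high values were FST 9.37, IL24 7.96, KITLG 8.37, LIPG 6.62, LOXL4 8.79, MANEAL 7.57, PTPRE 6.82, RBM24 11.09, RGS4 7.07, SDC2 7.13, WNT9A 9.05 and YPEL2 8.25. The low values there were AKAP12 9.74, ATP10D 6.22, GAS2L1 7.23, HBEGF 7.74, MT1X 11.17, PDLIM1 6.25, RHOB 9.31 and RHOU 3.49.

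The 6 other single values were ATP10D 7.20 in CMV replicate 1, LOXL4 4.88 in CMV replicate 2, PDLIM1 6.13 in CMV replicate 3, KDM4B 7.45 in CMV replicate 4, MANEAL 5.75 in CMV replicate 5 and KLF12 7.55 in ERb replicate 4.

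The values of the arrays labelled ERb replicate 6 and ERbDBD replicate 6 are consistent with an exchange of their labels. Among 225 genes that differed between ERb and ERbDBD without these arrays, 84.4% placed ERb replicate 6 and 80.9% placed ERbDBD replicate 6 nearer to the other label, while for the other arrays, each placed on 155 to 188 genes chosen without it, the highest share was 20.7% (ERbDBD replicate 3). Weak infection of ERb replicate 6 is argued against, since genes changed by the mutant alone lay at 0.840 of the way from CMV to the mutant (0.734 to 0.935) and ESR2 was 9.22, above the other ERb arrays (8.44 at most). A large share of ERb RNA in ERb replicate 6 is argued against by a median share of ERb signal of -0.00768 (-0.0940 to 0.127). The interval was resampled over 23 genes of that 1 array, and a mix with a share inside it is not excluded. Exchanging these 2 arrays gave 251 genes between ERb and ERbDBD and the other 35 single exchanges at most 10; the exchange stays a hypothesis found and tested on the same data, and a real response of both cultures was not tested.

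Metallothioneins were higher on the arrays labelled ERbDBD, with both arrays of number 6 left out. A zinc response through MTF-1 was not decided. The median of 5 measured other targets was SLC39A10 at -0.0283 (-0.13 to 0.07), below the limit set beforehand. That limit was 0.424, which is 0.5 times the smallest metallothionein change. By the rule written beforehand, this interval of the median counted against a zinc response. SLC30A1 rose by 0.28 (0.13 to 0.44, limma adjusted p = 0.0450), and its interval reached above the limit. HMOX1 at -0.57, GCLC at -0.31 and SELENOH at 0.30 did not pass. The 5 targets went both ways, so, judged after the outcome, their median is not taken to decide the question. A glucocorticoid-type response stays open, since 20 measured genes of a list of 33 had a median difference of 0.0341 between ERbDBD and ERb (camera p = 0.196 with an estimated correlation). The members' signals within groups correlated at a median of 0.928 (0.814 to 0.968), which shared probe targets could give and common regulation could give as well, and which does not account for the rise.

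Other splits of the samples were counted for each comparison, 100 drawn each time with the real one included. For ERb against CMV 1 of 100 gave as many genes as the real 108, with 1 gene as the highest other, and for ERbDBD against CMV 1 of 100 (real 65, highest other 1). With 100 drawn, 1 in 100 is the smallest share possible, so random grouping is unlikely for both counts and not excluded. The splits cannot separate the receptor from any other difference between CMV and receptor arrays. For ERb against ERbDBD 100 of 100 gave as many as the real 0, which any split must, so this count says nothing about chance; the highest other, 10, had ERb replicates 1 to 5 and ERbDBD replicate 1 on one side. Without both arrays of number 6, the shares were 1 of 100 for ERb against CMV (real 280, highest other 118), 2 of 100 for ERbDBD against CMV (real 204, highest other 383) and 1 of 100 for ERb against ERbDBD (real 225, highest other 1). The split with 383 genes put CMV replicates 3, 4 and 6 with ERbDBD replicates 2 and 3. This 1 grouping other than the labels gave more genes than the real one. Its sides did not overlap in signal level, looked at after the outcome. The upper quartile of intensity was at most 17.94 on the side named and at least 18.03 on the other. The filter level was reached by at most 22.93% of probe sets against at least 22.95%. The axis of largest spread among the arrays (27.9% of variance) parted them too. Values there were -0.0078 or higher against -0.18 or lower. Whether this signal difference gave the 383 genes was not tested. The share of 1 of 100 for ERb against ERbDBD rests on arrays left out for their values. Of the 16 splits that part the 2 arrays of every number only the real one reached 225. The highest other was 0, but 1 in 16 is the smallest share possible there.

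A test of the difference itself gave 225 genes between ERb and ERbDBD without both arrays of number 6, against 0 as labelled (limma, 399 with an unadjusted p below 0.05). Among 1541 kept probe sets without a single gene symbol, which the comparisons of genes do not use, 13 passed in ERb against CMV and 11 in ERbDBD against CMV.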

How the results depend on the processing

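Leaving out both arrays of number 6, with or without the replicate block, was chosen only after the result was seen; the other settings were fixed before the data were examined. No called result reversed its direction: of 1789 values of 46 called named results under other settings, 1510 kept direction and side of the threshold and 279 kept direction alone. Some settings cannot change a log2 value, such as a stricter threshold or leaving out an array of the third group. Part of this count was therefore fixed in advance. For ERb against CMV (108 genes) the count was 176 over every probe set, 333 with array weights, 14 at 2-fold or more, 51 at an adjusted p of 0.01 and 280 with both arrays left out. For ERbDBD against CMV (65) it was 110 with the replicate number as a random effect, 42 with only these groups fitted, 41 without a filter, 106 over every probe set, 152 with array weights, 4 at 2-fold, 28 at 0.01 and 204 with both arrays left out. For ERb against ERbDBD (0) it was 197 with array weights and 225 with both arrays left out, and 0 under the other planned settings that kept all arrays. Genes called in both against CMV in the same direction (39) numbered 59, 63 and 63 with the random effect, every probe set and array weights, 2 at 2-fold, 20 at 0.01, 59 with both arrays left out and 11 with CMV arrays split. Leaving out single arrays or replicate numbers gave 44 (without number 4) to 256 (without number 6), 25 (number 2) to 167 (number 6), 0 to 220 (number 6) and 20 (number 2) to 53 (number 6) in the same order; leaving out a number removes 3 arrays. The stricter thresholds lower counts by construction, and splitting the CMV arrays leaves fewer controls in each comparison. Leaving out arrays lowered counts in some fits and raised them in others, and for these and the remaining settings the cause was not tested. With the replicate number as a block (replicate block) the counts were 121, 74, 0 and 50. With both arrays left out and the block they were 304, 204, 241 and 69. Numbers paired ERb with ERbDBD but neither with CMV. Between the receptors no gene was called as labelled with or without the block. With both arrays left out the block kept 49 of 55 called genes that were named or in a list, all 16 largest changes among them, and lost ERRFI1 (adjusted p = 0.102) and 5 list members (JUN, PHLDA1, PMEPA1, VEGFA and ZMAT3, adjusted p from 0.0501). Against CMV, where the block has no such support, MANEAL in ERb (adjusted p = 0.0630) and RHOB, RHOU and MT1X in ERbDBD (adjusted p from 0.0564 to 0.108) did not pass with it. With both arrays left out C3, TGFA, SDC2, MIR146A and ZMAT3 in ERb and ATP10D, CXCL3, PLK2, PMEPA1, SDC2 and VPS26C in ERbDBD did not (adjusted p from 0.0528 to 0.172). As labelled, the call of classical estrogen receptor targets in ERb against CMV was lost with an estimated correlation (adjusted p = 0.265) and with fry (adjusted p = 0.0668). With both arrays left out it was lost with an estimated correlation (adjusted p = 0.170) and kept with fry (adjusted p = 0.0125). Signal near background limits the folds of dim genes.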

Other observations

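The list of glucocorticoid-inducible genes was written only after the largest changes were seen, and before it was tested.

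Genes known to be induced by glucocorticoids, of which 20 of 33 were measured, stood higher than CMV as a set in both receptor groups as labelled, with 12 of the 20 positive in each. In ERb the median was 0.03 with 2 members called over all genes and 3 adjusted over the list alone (camera p = 0.00118, p = 0.00298 with an estimated correlation). In ERbDBD the median was 0.13 with 1 called and 5 adjusted over the list alone (camera p = 1.73e-05, p = 0.000290 with an estimated correlation). With arrays centred on their medians 1 was called in ERb and 0 in ERbDBD, and after quantile normalization 3 and 0 (limma). With both arrays of number 6 left out, 11 of the 20 were positive in ERb, at a median of 0.02 (camera p = 0.00590, p = 0.0118 with an estimated correlation). With arrays also centred on their medians 10 were positive (median 0.01), and after quantile normalization 10 (median 0.004). The set result in ERb thus rested on part of the list. In ERbDBD 13 were positive, at a median of 0.09 (camera p = 1.73e-05, p = 0.000525 with an estimated correlation). In that setting 3 rose in ERb: SPSB1 (log2 0.71), ERRFI1, a feedback inhibitor of the epidermal growth factor receptor (0.42), and IRS2, an insulin receptor substrate (0.15). In ERbDBD 4 rose: the kinase gene SGK1 (0.55), the transcription factor gene CEBPB (0.40), the immunophilin gene FKBP5 (0.21) and IRS2 (0.19). The direct comparison gave SPSB1 0.67 and ERRFI1 0.23 higher in ERb (ERRFI1 did not pass with the replicate number as a block, adjusted p = 0.102) and FKBP5 -0.23 lower, while SGK1 at -0.44 did not pass. The list as a set did not separate the receptors, with camera p = 0.196 with an estimated correlation.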
